A study of Homo sapiens with 18 samples.

How the data were processed

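The series measured RNA of HK-2 cells, an immortalized human line of renal proximal tubular epithelial cells, after control treatments used in a wider study of kidney toxicity. Total RNA was hybridized as biotin-labelled cRNA to Affymetrix HG-U133 Plus 2.0 arrays. There were 18 arrays in 6 groups of 3 biological replicates: medium, DMSO and ethanol, each for 24 h and 48 h. The sample labels give 24 h and 48 h, whereas the text on the series gives 12 h in place of the shorter time. The sample labels were used. Cells had been seeded 24 h before treatment, were treated at about 90% confluency, and grew with EGF at 10 ng/ml, hydrocortisone at 36 ng/ml, insulin at 5 µg/ml and glucose at 5 mM. The doses of DMSO and ethanol were not given in the sources used here. The compounds of the wider study were not analysed here.

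The deposited values are log2 expression made by the authors with GCRMA, which corrects background by probe GC content, makes array distributions alike and summarises each probe set. Its version and the arrays normalized together were not given in the sources used here. The log2 scale is not named in the labels and was read from the values, which run from about 1 to 16 on each array. No raw intensities were used here. Array medians lay near 2.9, and about 40% of probe sets on each array were above a log2 value of 4. For arrays there is no read depth; the number of arrays limits the precision.

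The table held 54675 probe sets. Of these, 62 were controls, 41097 had exactly 1 gene, 1801 had several genes and 11721 had no listed gene. Symbols of 41043 probe sets were taken through their gene identifier from the current RefSeq gene table, and 54 were kept from the platform table. A probe set entered where its value was above 4 on at least 3 of the 18 arrays, and 19730 probe sets with 1 gene did so. Each gene was represented by its probe set with the highest mean over the 18 arrays, chosen without the groups, which left 10832 genes. Genes whose signal stayed under that level were not tested. Where the mean of a group lies under 4 the probe set is near background, so the size of a difference is not exact and ranks by size are approximate.

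Differences were tested with limma 3.58.1 in R 4.3.3. Means of the 6 groups entered 1 fit with 12 residual degrees of freedom and 2.65 prior degrees of freedom from the empirical Bayes step. The 14 contrasts were DMSO and ethanol against medium at each time and averaged over both times, DMSO against ethanol at each time, 48 h against 24 h in each control and averaged over the 3, and the difference in time change between DMSO and medium and between ethanol and medium. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene passed under an adjusted p of 0.05. They measure the spread between biological replicates as the labels name them, pooled over all 6 groups. Errors beside log2 differences are standard errors from that fit, and n is 3 arrays per group unless stated. Standard deviations are given beside group means.

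Replicate numbers are shared between the groups, so it was checked whether they pair the arrays. Deviations from group means were correlated across genes between arrays with the same number. The genes are not independent replicates. Among DMSO and medium groups these correlations lay between 0.526 and 0.731. They were above the threshold of 0.1 for ethanol at 24 h as well, and for ethanol at 24 h with ethanol at 48 h, but not between ethanol at 48 h and DMSO or medium groups. Between both ethanol times the pairing rests on replicate 3, at 0.680, and the difference of replicate 1 and 2 correlated at -0.135, so the block is weakly founded there. Where the numbers paired the arrays compared, a value with the replicate number as a block is given beside the result.

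Before the data were examined, 35 gene lists and 6 lists of cell type markers were fixed, with 702 genes, of which 629 had a probe set. The lists cover proliferation, stress responses, metabolism, matrix, inflammation and kidney injury, among others. Lists not named in the results were not called by camera in any comparison of the main fit of 18 arrays. The 38 lists with at least 3 tested members were tested with camera from limma at its preset correlation between genes of 0.01, adjusted over the 38 lists. Camera with an estimated correlation was run as well, and so was fry, which asks if the members move on balance one way. Fry calls are given only in the part on processing. Every camera call in the 18-array fit was lost with an estimated correlation, so list calls are given with that p. Counts of members that passed use the adjusted p over all genes, and where stated the p adjusted over the list alone.

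Genes to name were also set by a rule fixed before the data were examined. Among genes that passed without overlap between the groups of arrays (for averaged contrasts, with the same direction in each pair), the rule takes the 10 largest rises and the 10 largest falls, plus up to 4 passing members per list. Where none passed, the 5 genes with the smallest p are given as values. HAVCR1, LCN2, CLU, SPP1, HMOX1, CYP1A1, MKI67 and CDKN1A are given for each solvent against medium as common readouts of kidney cell injury, stress, exposure to foreign chemicals and proliferation. Further members of the fixed lists are named as examples. Members beyond the rule, and genes named from the 12-array fit or as above the level on ethanol arrays only, were chosen after their values were seen.

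Alternatives fixed before the data were examined were a replicate block, a fit of only the groups compared, array weights, trend and robust empirical Bayes, no level filter and one at 6, the mean of a gene's probe sets, each probe set on its own, a 2-fold threshold, median centring, quantile normalization and leaving out each array. Alternatives without both arrays of ethanol replicate 3, with and without the block, and a blocked fit of the 12 DMSO and medium arrays were added after the data were seen. The steps were tested on simulated data built from the residual spread, with 200 changed genes in each of 10 simulations of ethanol against medium at 48 h. The test recovered 20% of genes set at a log2 change of 0.5, 68.5% at 1 and 94.5% at 2, and 5.66% of calls were false. The simulated noise was normal, independent and equal in spread in all groups. The data had a larger spread with ethanol and shared replicate deviations, so 5.66% is not the false share of the real calls.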

Results

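The data were gene expression profiles of HK-2 cells kept in medium alone or in medium with DMSO or ethanol, the solvents in which test compounds are dissolved. Each control was measured after 24 h and 48 h on 3 arrays, 18 in all. The arrays had alike signal: 39.7% to 40.3% of probe sets were above a log2 value of 4, and array medians lay between 2.86 and 2.95. Of 10832 genes tested, 541.6 are expected at an unadjusted p under 0.05 by chance. Both arrays of ethanol replicate 3 stood apart from the others on the second principal component, which held 30.7% of the variance. Their scores were -52.3 at 24 h and -61.6 at 48 h, and the other 16 arrays lay between -21.2 and 20.5.

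The comparison of DMSO with medium asks if this solvent alone changes the cells. At 24 h and at 48 h, the expression of kidney injury and stress genes was close in both. HAVCR1, which encodes the injury marker KIM-1, was at a log2 value of 11.29 ± 0.10 with DMSO and 11.26 ± 0.10 in medium at 24 h (SD, n = 3), a difference of 0.04 ± 0.15. The difference was 0.05 ± 0.15 at 48 h. HMOX1, which encodes heme oxygenase, differed by 0.13 ± 0.26 at 24 h and 0.15 ± 0.26 at 48 h. MKI67, a marker of cycling cells, differed by 0.19 ± 0.24 and 0.17 ± 0.24. CLU, SPP1 and CDKN1A all differed by at most 0.10 in size at either time. LCN2 differed by -0.07 ± 2.16 and 0.05 ± 2.16, but its means lay under the level of 4 in all these groups. It entered the test through 3 ethanol arrays only, so its small difference says little. CYP1A1, a gene induced through the aryl hydrocarbon receptor, was below the level for testing, with a highest value of 2.13 on any array.

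With limma no gene passed between DMSO and medium, while 204 genes at 24 h and 53 at 48 h had an unadjusted p under 0.05. Both counts lie under the 541.6 expected by chance, so these p-values run large. The fit takes its spread from all 6 groups and leaves out the replicate pairing. At 24 h and 48 h the median SD per gene was 0.153 and 0.171 with DMSO, 0.153 and 0.160 in medium, and 0.219 and 0.263 with ethanol. The pooled spread can thus be too large for DMSO against medium and too small for contrasts with ethanol, whose p-values can run small. The smallest p-values at 24 h belonged to RTKN2 at -0.92 ± 0.17, the mitochondrial gene ND6 at -0.68 ± 0.14, GNAO1 at 0.66 ± 0.13, SEC24D at -0.69 ± 0.15 and the noncoding HLA-F-AS1 at -0.71 ± 0.16, none of which passed. At 48 h they belonged to XRCC2 at -0.70 ± 0.17, TMEM151B at 0.57 ± 0.20, XBP1 at -0.37 ± 0.11, WRN at 0.37 ± 0.12 and RPL7AP10 at -0.34 ± 0.12. Averaged over both times no gene passed either (239 at an unadjusted p under 0.05), and the smallest p-values belonged to ND6 at -0.48 ± 0.10, HLA-F-AS1 at -0.54 ± 0.11, RPL7AP10 at -0.39 ± 0.08, RTKN2 at -0.53 ± 0.12 and ARHGAP5 at -0.46 ± 0.11 (n = 6 arrays per side). The averaged differences were 0.04 ± 0.11 for HAVCR1, 0.14 ± 0.19 for HMOX1, 0.18 ± 0.17 for MKI67 and at most 0.02 in size for LCN2, CLU, SPP1 and CDKN1A. No list member passed in any of the 3 comparisons, and adjusted over the list alone 1 member of the unfolded protein response list was lower in the average. Camera called 2 lists at 48 h with small medians: the amino acid and integrated stress response list at -0.11 and the mitotic list at 0.11, both with an adjusted p = 0.901 with an estimated correlation. The same 2 lists were called in the average over both times, with an adjusted p = 0.990 with an estimated correlation, and there the stress list was lost with the replicate block (adjusted p = 0.0856) and without both ethanol replicate 3 arrays (adjusted p = 0.0519). The stress list call turned to the other direction without medium 48 h replicate 1, with adjusted p = 0.760 at 48 h and 0.903 in the average.

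DMSO and medium arrays shared their replicate differences closely, and the counts with the replicate block in the 18-array fit were 0 as well. A blocked fit of the 12 DMSO and medium arrays was chosen after the data were seen. In it 11 genes passed at 24 h (2 higher, 9 lower), 0 at 48 h and 12 in the average (4 higher, 8 lower). At an unadjusted p under 0.05 there were 1231, 605 and 1495 genes, where 541.6 are expected by chance. None of the genes that passed reached 2-fold. ACSL4, which activates long-chain fatty acids, was lower by a log2 difference of -0.83 ± 0.09 at 24 h (adjusted p = 0.0304), ND6 by -0.68 ± 0.08 (adjusted p = 0.0375) and ARHGAP5 by -0.64 ± 0.07 (adjusted p = 0.0304). The 28S rRNA control probe set also differed at 24 h, at 7.94 ± 0.36 with DMSO and 9.39 ± 0.39 in medium (SD, n = 3).

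**Figure D1:**
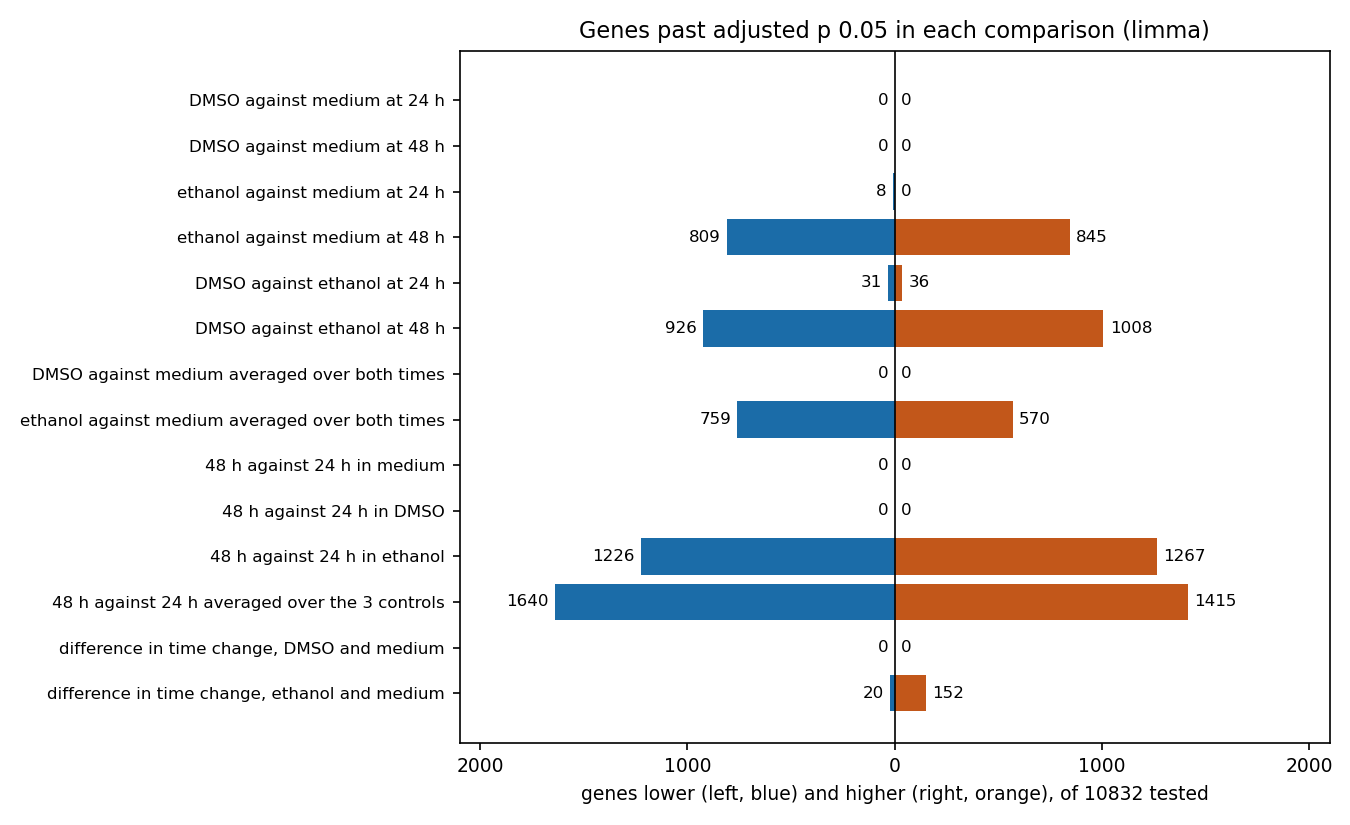
Number of genes past an adjusted p of 0.05 in each comparison, out of 10832 tested, with genes lower in the first-named group to the left and genes higher to the right. Ethanol against medium at 48 h has 845 higher and 809 lower genes, and DMSO against medium has 0 at each time.

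Ethanol against medium at 24 h asks the same of the other solvent. After 24 h few genes passed, all of them lower with ethanol. TAGLN, which encodes the actin-binding protein transgelin, fell by 2.77 ± 0.46 on the log2 scale, from 5.78 ± 1.41 in medium to 3.00 ± 0.40 with ethanol (SD, n = 3). SSH1, a phosphatase that activates cofilin, fell by 1.00 ± 0.16, and CDC42EP3, an effector of CDC42, fell by 1.06 ± 0.18. MTSS2 fell by 2.15 ± 0.34. TAGLN, MTSS2 and RTKN2 lay under the level of 4 with ethanol, so the sizes of these falls are not exact. RTKN2, UBASH3B, DPY19L1 and WIPF2 fell by 0.65 to 1.00. These 8 genes, all lower and 5 of them by 2-fold or more, were those that passed, with adjusted p between 0.0486 and 0.0497, while 965 genes had an unadjusted p under 0.05.

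Inflammatory genes at 24 h were uneven between the ethanol arrays. The NF-kB and inflammatory cytokine list had a median log2 difference of 0.78 over 17 tested members, of which 0 passed, also when adjusted over the list alone. The camera call had an adjusted p = 0.691 with an estimated correlation and was lost without both ethanol replicate 3 arrays (adjusted p = 0.840). In the TGF-beta and matrix list 1 of 19 members fell, TAGLN, and 3 fell when adjusted over the list alone, with a median of -0.53 (adjusted p = 0.429 with an estimated correlation). Cholesterol synthesis (median 0.13), housekeeping (0.08) and hypoxia (0.23) lists were also called, with 0 members passing and adjusted p = 0.604, 0.334 and 0.334 with an estimated correlation. The cholesterol and housekeeping calls were lost without both ethanol replicate 3 arrays (adjusted p = 0.248 and 0.192). Without those arrays camera called 8 lists, where it called 5 with all arrays. LCN2, which encodes the injury marker NGAL, differed by 2.89 ± 2.16, HAVCR1 by -0.23 ± 0.15, CLU by 0.24 ± 0.29, SPP1 by 0.22 ± 0.10, HMOX1 by -0.08 ± 0.26, MKI67 by 0.01 ± 0.24 and CDKN1A by -0.16 ± 0.27, and none passed.

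The 28S rRNA control was at 10.58 ± 0.24 with ethanol at 24 h, above the 9.39 ± 0.39 in medium. With the replicate block 111 genes passed (22 higher, 89 lower), among them all 8, and without both ethanol replicate 3 arrays 144 passed (52 higher, 92 lower), again among them all 8. The call of these 8 genes rests on its settings: 0 genes passed after quantile normalization, after median centring, with trend and robust empirical Bayes, with only both groups in the fit, and without medium replicate 1, ethanol replicate 1 or ethanol replicate 2. The count was 2 without medium replicate 2, 1 without medium replicate 3 and 40 without ethanol replicate 3. Array weights gave the highest count, stated with the other alternatives below.

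At 48 h, ethanol cultures had a broad rise of endoplasmic reticulum stress genes against medium. HSPA5, the main chaperone of that compartment, was 2.38 ± 0.18 higher on the log2 scale (adjusted p = 2.3e-06). SDF2L1, a partner of chaperones there, rose by 4.36 ± 0.44, a 20.6-fold difference, from 6.31 ± 0.21 to 10.68 ± 1.10 (SD, n = 3). DDIT3, the stress transcription factor CHOP, rose by 3.49 ± 0.47, from 9.53 ± 1.19 to 13.02 ± 0.49, and ATF3 rose by 4.40 ± 0.71, a 21.2-fold difference. In the other direction FASN, the fatty acid synthase, fell by 2.11 ± 0.29, and CLDN2, a channel-forming claudin of the proximal tubule, fell by 2.64 ± 0.66.

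In all, 1654 genes passed at 48 h, 845 higher and 809 lower with ethanol, and 396 reached 2-fold. Of the unfolded protein response list, 18 of 19 members rose, with a median of 1.79. They include DNAJB9 at 2.71 ± 0.23, CRELD2 at 2.65 ± 0.38 and MANF at 2.62 ± 0.24. Of the amino acid and integrated stress response list, 18 of 22 rose, with a median of 1.42. NUPR1 rose by 3.58 ± 0.24 from under the level of 4, the cystine transporter gene SLC7A11 by 2.48 ± 0.39 and CTH, an enzyme of cysteine synthesis, by 2.41 ± 0.33. Both camera calls had an adjusted p = 0.131 with an estimated correlation, and the same 18 and 18 counts were found when adjusted over the list alone.

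Cell cycle genes were lower with ethanol at 48 h. Of 30 mitotic genes 16 fell (22 when adjusted over the list alone), with a median of -0.61. PLK1, a mitotic kinase, fell by 1.56 ± 0.30, AURKA by 0.91 ± 0.21 and CCNA2 by 0.91 ± 0.22. Of 26 DNA replication genes 15 fell and 1 rose, with a median of -0.59 (17 and 1 adjusted over the list alone). UHRF1 fell by 1.38 ± 0.31 and the helicase gene MCM4 by 1.06 ± 0.18, and the licensing factor CDC6 rose by 1.10 ± 0.33. Both lists had an adjusted p = 0.434 with an estimated correlation. MKI67 was 0.86 ± 0.24 lower (adjusted p = 0.026).

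Metabolic lists were lower with ethanol at 48 h as well. Of 8 fatty acid synthesis genes 5 fell (7 adjusted over the list alone), with a median of -0.63, among them FASN, SREBF1 at -0.95 ± 0.21 and SCD at -0.64 ± 0.18 (adjusted p = 0.131 with an estimated correlation). Of 21 oxidative phosphorylation genes 8 fell (11 adjusted over the list alone), with a median of -0.34, such as ATP5MC1 at -0.91 ± 0.14 and SDHA at -0.60 ± 0.09 (adjusted p = 0.207 with an estimated correlation). Of 15 glycolysis genes 4 fell, PKM, TPI1, PGAM1 and LDHA, by 0.61 to 0.96 (adjusted p = 0.434 with an estimated correlation). Of 8 genes of alcohol and aldehyde metabolism 2 fell, the mitochondrial aldehyde dehydrogenase gene ALDH1B1 by 1.51 ± 0.28 and ACSS2, which makes acetyl-CoA from acetate, by 0.88 ± 0.25 (adjusted p = 0.434 with an estimated correlation). Of 12 heat shock genes 4 fell, HSPE1, HSPB1, HSPH1 and HSP90AA1, by 0.38 to 0.64 (adjusted p = 0.434 with an estimated correlation). The lysosome and autophagy list had 3 rises, WIPI1, MAP1LC3B and SQSTM1, and 1 fall, NPC2 (adjusted p = 0.434 with an estimated correlation), and its call was lost without both ethanol replicate 3 arrays (adjusted p = 0.103).

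Camera called the NF-kB and cytokine list higher with ethanol at 48 h, with few members passing. Of its 17 members 3 rose (4 adjusted over the list alone): TNFAIP3, a feedback inhibitor of NF-kB, by 2.62 ± 0.83, the adhesion molecule gene VCAM1 by 1.53 ± 0.35 and RELB by 0.87 ± 0.26. The list median was 0.94 (adjusted p = 0.564 with an estimated correlation). Both ethanol replicate 3 arrays stood apart in this list, with a median 1.83 above the 12 DMSO and medium arrays. VEGFA rose by 1.69 ± 0.20, the growth factor gene EREG by 3.06 ± 0.68, GDF15 by 1.80 ± 0.42, and LOX, a collagen crosslinking enzyme, by 2.39 ± 0.62. Of the largest rises, SCG5 (4.77 ± 1.34), MIR146A (3.84 ± 1.07), ALDH1L2 (3.77 ± 0.28), ERO1B (3.54 ± 0.43), ITPKA (3.43 ± 0.59) and BEX2 (3.31 ± 0.24) have not been named so far. SCG5, RELB and the probe set assigned to the microRNA gene MIR146A were under the level of 4 in medium, and OLFML2A below was so with ethanol, so these sizes are not exact. The largest falls were CNNM1 at -2.84 ± 0.55, TUBB4A at -2.72 ± 0.40, CLDN2, OLFML2A at -2.59 ± 0.60, FASN, ECM1 at -2.08 ± 0.39, SLFN13, BRINP1, VSIG10L and LRRN4. Among the fixed injury readouts HAVCR1 fell by 0.62 ± 0.15 (adjusted p = 0.013), and LCN2 at 4.90 ± 2.16 (adjusted p = 0.14), HMOX1 at 0.50 ± 0.26, CDKN1A at 0.29 ± 0.27, CLU at -0.12 ± 0.29 and SPP1 at -0.03 ± 0.10 did not pass. SPP1 was 0.61 higher and passed (adjusted p = 0.0177) where the mean of its probe sets was used.

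At 48 h the 28S rRNA control was at 10.16 ± 0.17 with ethanol and 9.71 ± 0.23 in medium, and the difference between 3' and 5' actin probe sets was 0.89 ± 0.23 and 0.90 ± 0.23 (SD, n = 3). Without both ethanol replicate 3 arrays 1879 genes passed, of which 1315 were shared with the 1654. The count was 861 without medium replicate 3, 1053 without medium replicate 1 and 114 with only both groups in the fit.

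**Figure D2:**
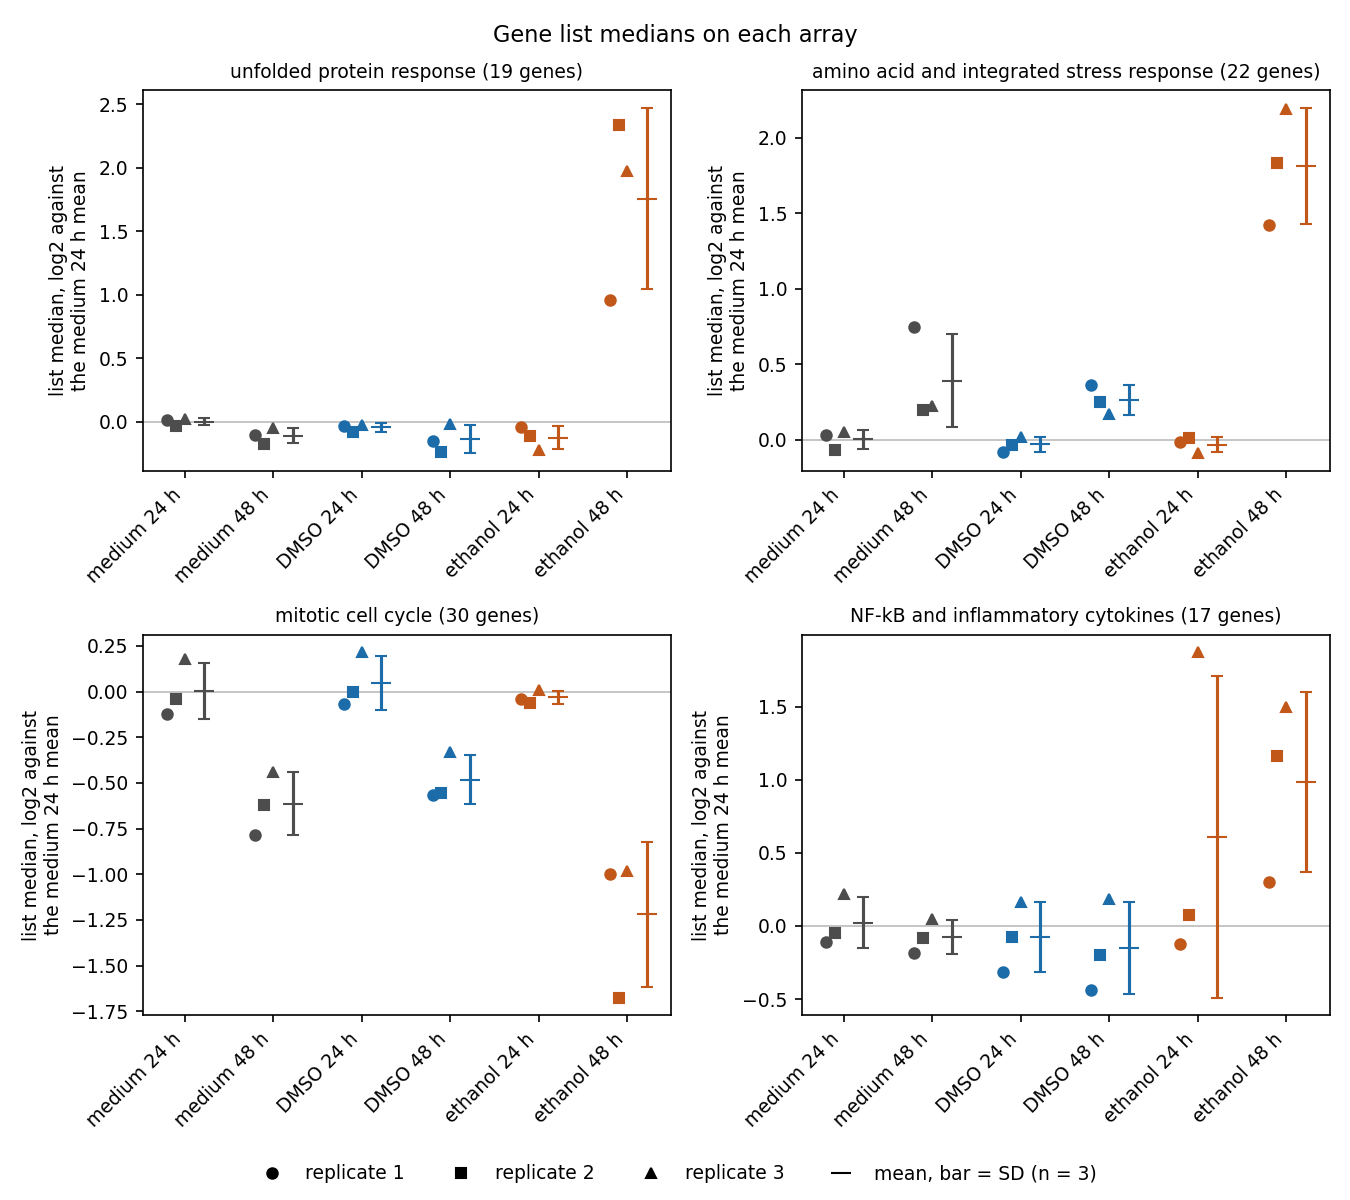
Median of 4 gene lists on each array, as log2 difference from the mean of the medium 24 h arrays, with the 3 replicates of each group as points and the group mean and SD beside them. The unfolded protein response list lies between 0.96 and 2.34 on the ethanol 48 h arrays and between -0.24 and 0.02 on the other 15.

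Ethanol against medium averaged over both times gave 1329 genes, 570 higher and 759 lower (n = 6 arrays per side). THBS1 (-1.66 ± 0.39), TAGLN (-1.54 ± 0.33) and CCN2 (-1.11 ± 0.31) of the TGF-beta and matrix list fell, as did TLN1 (-1.50 ± 0.24), EPPK1 (-1.64 ± 0.41), TUBB4A (-1.98 ± 0.28), CLDN2 (-1.95 ± 0.47) and MTSS2 (-1.89 ± 0.24). SCG5 (3.54 ± 0.95), MIR146A (3.14 ± 0.76), the cadherin gene CDH11 (2.61 ± 0.64) and ATF3 (2.49 ± 0.50) were among the genes that rose. SCG5, MIR146A and CDH11 in medium, and TAGLN and MTSS2 with ethanol, were under the level of 4, so their sizes are not exact. The replicates were uneven in these genes. At 24 h SCG5 was at 2.24 and 2.22 in ethanol replicate 1 and 2 and at 9.32 in replicate 3, MIR146A was at 3.17 in replicate 1 and 8.72 in replicate 3, and CDH11 was at only 2.60 and 2.86 on both replicate 3 arrays. Without both replicate 3 arrays the averages were 1.89 for SCG5, 1.84 for MIR146A, 3.68 for CDH11 and 1.72 for ATF3, and all 4 passed. Of the unfolded protein response list 13 of 19 rose, 16 when adjusted over the list alone, and of the amino acid and integrated stress response list 12 of 22, 15 when adjusted over the list alone (both adjusted p = 0.232 with an estimated correlation). The 48 h arrays carry the unfolded protein response average: in the means 4 of 19 members were higher with ethanol at 24 h and 19 at 48 h. Of 19 TGF-beta and matrix genes 6 fell and 0 rose, and camera did not call that list. Of the markers of other cell types, the fibroblast genes DCN (-1.11 ± 0.34) and LUM (-0.68 ± 0.19) and the podocyte gene PTPRO (-0.62 ± 0.13) fell as well, and the keratinocyte gene KRT10 (0.31 ± 0.08) rose. DCN was uneven too, at 11.14 and 12.21 in ethanol replicate 3 at 24 h and 48 h, where the mean of the other ethanol arrays was 10.27. The 12.21 was its highest value on any array. HAVCR1 fell by 0.43 ± 0.11 (adjusted p = 0.0199), while LCN2 at 3.89 ± 1.53, MKI67 at -0.42 ± 0.17, HMOX1 at 0.21 ± 0.19, SPP1 at 0.09 ± 0.07, CDKN1A at 0.06 ± 0.19 and CLU at 0.06 ± 0.21 did not pass. Mitotic (9 of 30 fell), fatty acid synthesis (4 of 8 fell), oxidative phosphorylation (5 of 21 fell), DNA replication (5 of 26 fell), heat shock (3 of 12 fell), glycolysis (3 of 15 fell), NF-kB (3 of 17 rose), hypoxia (3 of 16 rose) and lysosome lists (3 of 17 rose, 1 fell) were called, with adjusted p from 0.232 to 0.572 with an estimated correlation. The share of higher genes among those that passed was 42.9% here, 51.4% after quantile normalization and 53.4% after median centring. The count was 727 without medium 24 h replicate 1, 852 without medium 24 h replicate 3, 833 without medium 48 h replicate 1, 797 without medium 48 h replicate 3 and 2063 without ethanol 48 h replicate 1.

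DMSO against ethanol sets the solvents side by side. At 24 h TAGLN was 3.18 ± 0.46 higher with DMSO than with ethanol (6.18 ± 0.20 and 3.00 ± 0.40, SD, n = 3), MTSS2 1.91 ± 0.34 higher, both sizes inexact since their ethanol means lie under 4, and RAB11FIP3, an adaptor of recycling endosomes, 1.52 ± 0.21 higher. DSP, which encodes the desmosome protein desmoplakin, was 0.92 ± 0.19 higher. Lower with DMSO were HS3ST1, a heparan sulfate sulfotransferase, at -1.92 ± 0.40, HLA-F-AS1 at -1.43 ± 0.16, TPMT, which methylates thiopurines, at -1.31 ± 0.21, ND6 at -1.24 ± 0.14 and RPL27A at -1.12 ± 0.11. In all, 67 genes passed, 36 higher and 31 lower with DMSO, 17 of them by 2-fold or more. TPMT had 1 of 2 probe sets with the opposite sign, and ARHGAP5 at -1.04 ± 0.15 had 2 of 4. B4GALT1 at -0.93 ± 0.18 had 2 of 3, so that its mean over probe sets was 0.09 and did not pass (adjusted p = 0.932).

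Lists called at 24 h between DMSO and ethanol were NF-kB and cytokines (median -0.77, 0 of 17 passing, 1 lower when adjusted over the list alone), housekeeping (-0.11, 0 of 12, 1 lower when adjusted over the list alone) and cholesterol synthesis (-0.17, 0 of 17), with adjusted p = 0.891, 0.379 and 0.891 with an estimated correlation. All 3 calls were lost without both ethanol replicate 3 arrays, where camera called 5 other lists. The 28S rRNA control was 7.94 ± 0.36 with DMSO and 10.58 ± 0.24 with ethanol. The replicate block gave 353 genes (225 higher, 128 lower), and 272 passed without both ethanol replicate 3 arrays, of which 62 were among the 67. Of the genes that passed, 53.7% were higher with DMSO, against 37.5% after quantile normalization and 42.3% after median centring. The count was 0 with only both groups in the fit, 5, 17 and 26 without DMSO replicate 1, 2 and 3, 36 and 8 without ethanol replicate 1 and 2, and 101 without ethanol replicate 3.

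At 48 h unfolded protein response and integrated stress response genes were lower with DMSO than with ethanol, and mitotic and DNA replication genes were higher, measured on the same ethanol arrays as the comparison with medium. ATF3 was 5.13 ± 0.71 lower on the log2 scale with DMSO, at 5.11 ± 0.14 against 10.23 ± 1.05 with ethanol (SD, n = 3). DDIT3 had a difference of -3.91 ± 0.47, the endoplasmic reticulum stress sensor gene ERN1 of -3.61 ± 0.46, and HERPUD1, which acts in the disposal of misfolded proteins, of -2.79 ± 0.18. INHBE, an inhibin beta subunit gene, had -3.83 ± 0.50. PLK1 was 1.65 ± 0.30 higher with DMSO, FASN 2.03 ± 0.29 and CLDN2 2.50 ± 0.66. In all, 1934 genes passed, 1008 higher and 926 lower, and 460 reached 2-fold.

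With DMSO at 48 h, 18 of 19 unfolded protein response genes (median -1.86) and 19 of 22 amino acid and integrated stress response genes (median -1.58) were lower than with ethanol, both with adjusted p = 0.146 with an estimated correlation. Of 30 mitotic genes 19 were higher (26 adjusted over the list alone; median 0.69) and of 26 DNA replication genes 15 were higher (18 higher and 2 lower adjusted over the list alone; median 0.62), both with adjusted p = 0.445 with an estimated correlation. Oxidative phosphorylation (8 of 21 higher) and fatty acid synthesis (5 of 8 higher) had adjusted p = 0.214 with an estimated correlation, and glycolysis (5 of 15 higher), heat shock (2 of 12 higher) and alcohol and aldehyde metabolism (2 of 8 higher) had 0.445. NF-kB and cytokines had 2 of 17 lower, TNFAIP3 and VCAM1 (9 lower adjusted over the list alone; adjusted p = 0.616 with an estimated correlation), and the lysosome list 5 of 17 lower and 1 higher (adjusted p = 0.445 with an estimated correlation), a call lost without both ethanol replicate 3 arrays (adjusted p = 0.0889). The 28S rRNA control was 8.92 ± 0.28 with DMSO and 10.16 ± 0.17 with ethanol at 48 h. The count was 1192 without DMSO replicate 1, 1098 without DMSO replicate 3 and 174 with only both groups in the fit.

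The time comparison in medium and in DMSO describes the cultures without ethanol. In the 18-array fit no gene passed with limma in either, while 1205 genes in medium and 1105 in DMSO had an unadjusted p under 0.05. The smallest p-values in medium belonged to ODF2 at -0.95 ± 0.17, RTKN2 at -0.92 ± 0.17, DPY19L1 at -0.72 ± 0.12, TAGLN at -2.48 ± 0.46 and SLC7A2, a transporter of cationic amino acids, at 1.24 ± 0.22. In DMSO they belonged to TAGLN at -3.05 ± 0.46, GPC6 at 1.12 ± 0.19, S100A2 at -1.28 ± 0.24, POMGNT2 at -0.77 ± 0.15 and SLC7A2 at 1.07 ± 0.22. TAGLN was under the level of 4 at 48 h in both. Adjusted over the list alone, 28 of 30 mitotic genes fell in medium and 22 in DMSO, with medians of -0.62 and -0.55 (adjusted p = 0.714 and 0.867 with an estimated correlation). DNA replication (medians -0.38 and -0.28), amino acid and integrated stress response (0.38 and 0.26) and TGF-beta and matrix lists (-0.38 and -0.29) were called in both, and heat shock (-0.17) in DMSO, all with adjusted p of at least 0.714 with an estimated correlation. With the replicate block the TGF-beta and matrix calls were lost in medium (adjusted p = 0.110) and DMSO (0.0643), as was heat shock in DMSO (0.0712). The count for medium was 2 without medium 24 h replicate 2 and 1 without medium 48 h replicate 1.

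With the replicate block, 438 genes passed between the times in medium (165 higher, 273 lower at 48 h) and 257 in DMSO (108 higher, 149 lower). In the blocked fit of the 12 DMSO and medium arrays, chosen after the data were seen, 3227 genes passed in medium (1357 higher, 1870 lower) and 3083 in DMSO (1456 higher, 1627 lower). All 30 mitotic genes fell in each, with adjusted p = 0.0408 and 0.0395 with an estimated correlation. DNA replication genes fell in 18 and 16 of 26 cases (adjusted p = 0.591 and 0.745 with an estimated correlation). BLNK, a signalling adaptor of B cells, rose by 3.53 ± 0.26 in both, INHBE by 2.27 ± 0.33 and 1.86 ± 0.33, and PLA1A, a phospholipase, by 1.71 ± 0.07 and 1.67 ± 0.07. TXNIP, an inhibitor of thioredoxin and glucose uptake, fell by 3.37 ± 0.67 and 2.74 ± 0.67, SLN, which encodes sarcolipin, by 3.13 ± 0.32 and 2.81 ± 0.32, the collagenase gene MMP1 by 3.04 ± 0.41 and 2.99 ± 0.41, and TNFAIP6 by 2.87 ± 0.29 and 2.92 ± 0.29. BLNK at 24 h and TNFAIP6 at 48 h were under the level of 4, so their sizes are not exact. Of the genes that passed, 2311 did so in the same direction in medium and DMSO, 1012 up and 1299 down, and 0 in opposite directions. Arrays with the same replicate number shared deviations in medium and DMSO, most of all at the same time, so the time changes are not independent and this overlap has no reference value here.

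In ethanol, 48 h against 24 h gave large changes of single genes. SLC7A11 rose by 5.32 ± 0.39, a 39.8-fold difference, from 5.11 ± 0.80 to 10.43 ± 0.23 (SD, n = 3). ATF3 rose by 5.09 ± 0.71, INHBE by 5.08 ± 0.50, DDIT3 by 4.87 ± 0.47 and HSPA5 by 2.60 ± 0.18. TXNIP fell by 3.29 ± 0.75, SLN by 3.20 ± 1.02, TM4SF4 by 2.69 ± 0.51 and PLK1 by 2.03 ± 0.30. SLN and TM4SF4 fell to under the level of 4. In all, 2493 genes passed, 1267 higher and 1226 lower at 48 h, and 671 reached 2-fold.

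All 30 mitotic genes fell with time in ethanol, with a median of -1.22 (adjusted p = 0.225 with an estimated correlation), and 21 of 26 DNA replication genes fell (23 fell and 1 rose adjusted over the list alone), with a median of -1.05 (adjusted p = 0.225 with an estimated correlation). MCM4 fell by 1.65 ± 0.18, UHRF1 by 1.81 ± 0.31, and the replication factor gene MCM10 by 2.32 ± 0.43. Of 19 unfolded protein response genes 17 rose (median 2.03, adjusted p = 0.225 with an estimated correlation), such as HERPUD1 at 3.16 ± 0.18 and DNAJB9 at 3.20 ± 0.23. Of 22 amino acid and integrated stress response genes 18 rose, 21 adjusted over the list alone (median 1.90, adjusted p = 0.125 with an estimated correlation). Oxidative phosphorylation (8 of 21 fell), glycolysis (6 of 15 fell), housekeeping (4 of 12 fell), fatty acid synthesis (4 of 8 fell), heat shock (3 of 12 fell), lysosome (6 of 17 rose) and cholesterol synthesis lists (4 of 17 fell, 2 rose) were called, with adjusted p from 0.225 to 0.555 with an estimated correlation. The calls of heat shock, lysosome, fatty acid and cholesterol synthesis were lost without both ethanol replicate 3 arrays. ACTB, often used as a reference gene, fell by 0.37 ± 0.12. The 28S rRNA control moved from 10.58 ± 0.24 to 10.16 ± 0.17. With the replicate block 3552 genes passed (1760 higher, 1792 lower at 48 h), though between both ethanol times the pairing rests on replicate 3, and the count was 95 with only both groups in the fit.

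**Figure D3:**
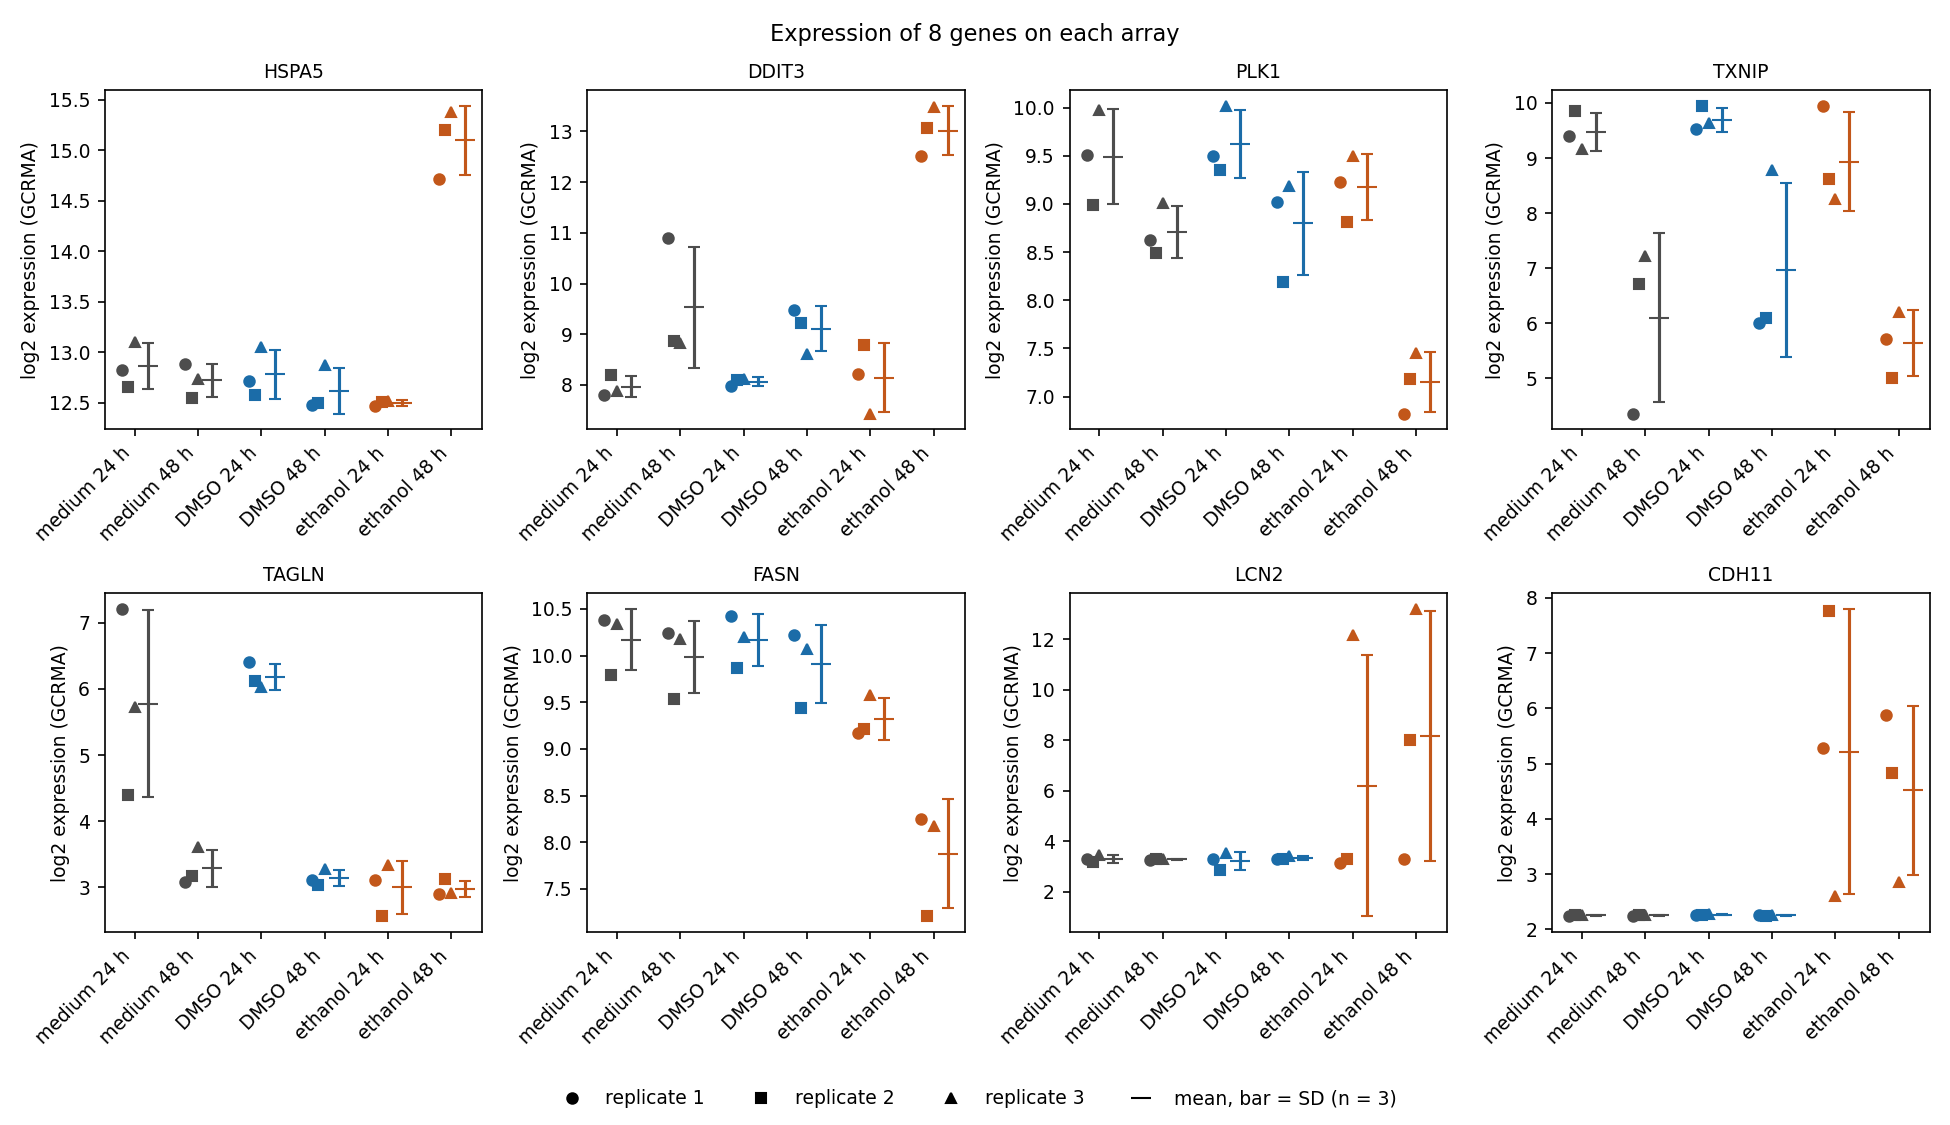
Log2 expression of 8 genes on each array, with the 3 replicates of each group as points and the group mean and SD beside them. HSPA5 lies above 14.7 on the 3 ethanol 48 h arrays, TXNIP is lower at 48 h in the mean of each control, and LCN2 is above 8 on 3 ethanol arrays only.

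Averaged over the 3 controls, 48 h against 24 h gave 3055 genes, 1415 higher and 1640 lower at 48 h (n = 9 arrays per side), and 151 reached 2-fold. TXNIP fell by 3.13 ± 0.43, SLN by 3.05 ± 0.59, GAL, which encodes galanin, by 2.26 ± 0.52, TM4SF4 by 2.26 ± 0.30, FOSL1, a subunit of AP-1, by 1.88 ± 0.55 and TAGLN by 1.85 ± 0.27. INHBE rose by 3.07 ± 0.29, BLNK by 2.98 ± 0.54, DDIT3 by 2.49 ± 0.27 and SLC7A11 by 2.42 ± 0.23. SLN, TM4SF4, FOSL1, TAGLN and BLNK were under the level of 4 in some groups. All 30 mitotic genes fell (median -0.79), as did 22 of 26 DNA replication genes with 1 rising (24 and 1 adjusted over the list alone; median -0.57), both with adjusted p = 0.392 with an estimated correlation. Of 22 amino acid and integrated stress response genes 18 rose (21 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation), and of 19 unfolded protein response genes 11 rose (14 adjusted over the list alone; adjusted p = 0.571 with an estimated correlation). Ethanol alone carries the unfolded protein response average: the median time change was 2.03 there, -0.0853 in medium and -0.110 in DMSO, and 19, 5 and 6 of 19 members were higher at 48 h in the means. Heat shock (6 of 12 fell), glycolysis (6 of 15 fell, 1 rose), oxidative phosphorylation (7 of 21 fell, 1 rose) and lysosome lists (5 of 17 rose) were also called, with adjusted p from 0.571 to 0.625 with an estimated correlation, and the lysosome call was lost without both ethanol replicate 3 arrays (adjusted p = 0.160) and oxidative phosphorylation with the replicate block (adjusted p = 0.0649). Of 17 kidney injury genes 3 rose, among them CLU by 0.66 ± 0.17, and 4 fell, among them SOX9 by 1.20 ± 0.39. With the replicate block 4278 genes passed, of which 3054 were among the 3055. HSPA4L, at -0.26 ± 0.06, had the opposite sign in the mean of its probe sets, at 0.03 (adjusted p = 0.794).

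The difference in time change asks if a solvent alters how the cells change between 24 h and 48 h. Between DMSO and medium no gene passed with limma. At an unadjusted p under 0.05 there were 26, under the 541.6 expected by chance, so these p-values run large too. The smallest p-values belonged to GNAO1 at -0.65 ± 0.19, RTKN2 at 0.79 ± 0.24, AGAP2-AS1 at -0.84 ± 0.27, SPRYD7 at 0.95 ± 0.30 and MYO5A at 0.44 ± 0.16, and no list was called. Between ethanol and medium 172 genes passed, 152 with a more positive and 20 with a more negative change in ethanol, and 123 by 2-fold or more. The change in SDF2L1 was 4.48 ± 0.63 larger in ethanol, that in SLC7A11 4.19 ± 0.55, in ALDH1L2 4.14 ± 0.40, in NUPR1 3.44 ± 0.34, in HYOU1 2.89 ± 0.49, in HSPA5 2.74 ± 0.25 and in ASNS, the asparagine synthetase gene, 2.47 ± 0.40. The change in ALDH1B1 differed by -1.74 ± 0.39, in the sterol regulator INSIG1 by -1.49 ± 0.30, in HMGCS1, an enzyme of cholesterol synthesis, by -1.47 ± 0.28, and in MCM4 by -1.19 ± 0.25. NUPR1 and ALDH1L2 were under the level of 4 in the 24 h groups.

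Of 19 unfolded protein response genes 12 had a more positive change in ethanol (18 adjusted over the list alone; median 1.92), and of 22 amino acid and integrated stress response genes 9 did (16 adjusted over the list alone; median 1.54), both with adjusted p = 0.0591 with an estimated correlation. DNA replication (2 of 26; adjusted over the list alone 12 more negative and 1 more positive), oxidative phosphorylation (2 of 21), cholesterol synthesis (2 of 17), glycolysis (1 of 15), housekeeping (1 of 12) and alcohol and aldehyde metabolism lists (1 of 8) were called with a more negative change. The mitotic and fatty acid synthesis lists were called in that direction with 0 members passing, and the lysosome list in the other with 1 of 17. These had adjusted p from 0.173 to 0.634 with an estimated correlation. Without both ethanol replicate 3 arrays 236 genes passed, and the lysosome call was lost. The count was 52 with only the 4 groups in the fit, and 108 and 89 without medium 24 h replicate 1 and 3. It was 99 and 89 without medium 48 h replicate 2 and 3, 103 without ethanol 24 h replicate 1, and 653 and 109 without ethanol 48 h replicate 1 and 2.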

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

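The tests of explanations in this part were all chosen after the values had been seen.

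A difference between groups drew attention to the time change in ethanol. With limma 172 genes changed differently between 24 h and 48 h in ethanol than in medium, and the median difference was 1.92 for the unfolded protein response list and 1.54 for the amino acid and integrated stress response list. Signals outside the gene comparisons drew attention as well. The 28S rRNA control probe set was 1.20 higher on the log2 scale with ethanol than in medium at 24 h. Among 2858 probe sets with no single gene, 298 changed between ethanol and medium at 48 h, 153 higher and 145 lower.

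The rise of the unfolded protein response in ethanol at 48 h was weighed first, and a single array is argued against, since the lowest list median among the 3 ethanol arrays was 1.01 above the medium mean and the highest among the 6 DMSO and medium arrays at 48 h was 0.112. A constant difference of the ethanol cultures is argued against too, with a median of -0.116 at 24 h. A stronger form of the usual time change is argued against by medians of -0.0853 in medium and -0.110 in DMSO, where it was 2.03 in ethanol. For the amino acid and integrated stress response list that explanation stays open, since the medians in medium and DMSO were 0.378 and 0.262 in the same direction. Whether ethanol itself or another condition of these cultures between 24 h and 48 h caused the rise could not be tested.

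Inflammatory genes on both ethanol replicate 3 arrays were weighed second, where the NF-kB list had a median 1.83 above the 12 DMSO and medium arrays, with 15 of 17 members higher. RNA from leukocytes is argued against, since the median difference of the leukocyte markers was -0.00503. An exchange of the 48 h array with a DMSO or medium array is argued against, since the highest unfolded protein response median on those 12 arrays was 0.129 and the lowest in ethanol replicate 1 and 2 at 48 h was 1.01. For an exchange of the 24 h array within that time, arrays were placed over 100 genes chosen without the array placed. The 24 h DMSO and medium arrays stood for 0. With ethanol replicate 1 and 2 as 1, the highest of the 6 DMSO and medium arrays was at 0.217. The lower and higher of ethanol replicate 1 and 2 were at 0.546 and 0.761 when held out. Their ethanol end held replicate 3, the array in question, so these places cannot decide on an exchange. On the scale ending at replicate 1 and 2, replicate 3 was itself at 0.0458, while its 28S control was with ethanol (10.61, the 12 others at most 9.93). So a wrong label or an outside sample stays open. A shared culture stays open too. Deviations of both replicate 3 arrays correlated at 0.680, but that restates the pattern, and the difference of replicate 1 and 2 gave -0.135 between the ethanol times. With replicate 3 of the DMSO and medium groups, deviations correlated at 0.305 to 0.480 for the 24 h array and 0.279 to 0.411 for the 48 h array. An outside sample does not predict such sharing, but no reference value was set for it.

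The distance of the ethanol arrays from the others was weighed last. If ethanol cultures were grown as a separate series, replicate differences should not be shared with DMSO and medium. The highest correlation of the difference between replicate 1 and 2 was 0.207 with ethanol, against 0.528 to 0.663 among DMSO and medium groups, but it was -0.135 even between both ethanol times. For ethanol at 24 h with DMSO and medium groups, deviations of arrays with the same number correlated at 0.149 to 0.480, and with other numbers at most at 0.160. Each array there correlated best with its own number. A wholly separate series does not predict this sharing at 24 h, though it was weaker than among DMSO and medium groups. At 48 h the same numbers gave -0.0834 to 0.411 and other numbers up to 0.347, so the explanation stays open. At 48 h a difference in RNA preparation marked by the 28S control is argued against as the sole cause. That control differed by -0.786 between DMSO and medium, where 0 genes passed, and by 0.458 between ethanol and medium, where 1654 passed. For 24 h that explanation stays open. The control differed by -1.45 for DMSO and 1.20 for ethanol against medium, and 11 genes passed for DMSO in the blocked fit of 12 arrays.

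Regrouping the arrays asks whether counts of this size arise by chance. With 3 arrays against 3 there are 10 groupings, too few to tell. The real grouping was the highest, 1 of 10, for ethanol against medium at 24 h (8 genes, highest other 0) and 48 h (1654, highest other 2), DMSO against ethanol at 24 h (67, highest other 0) and 48 h (1934, highest other 1), and time in ethanol (2493, highest other 677). For DMSO against medium at 24 h and 48 h and for time in medium and in DMSO the count was 0 in all 10 of 10 groupings, and since any grouping reaches 0 this tests nothing.

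Of 100 groupings drawn for each remaining comparison, 1 of 100, the real one, reached the count for ethanol against medium averaged (1329, highest other 1167) and for time averaged (3055, highest other 1135). All 100 of 100 reached the 0 genes of DMSO against medium averaged and of its difference in time change, each with a highest other of 1, which tests nothing, since any grouping reaches 0. For the difference in time change between ethanol and medium 8 of 100 reached 172, with a highest other of 749, which points to a structure of the samples. By that share chance is not excluded. The 7 others kept the 48 h arrays in place and so kept the ethanol difference at 48 h. A count of 172 thus did not need the real grouping of the 24 h arrays. The highest among 87 that regrouped the 48 h arrays was 171.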

How the results depend on the processing

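The alternatives here were chosen before the data were examined, except those without both ethanol replicate 3 arrays and the blocked fit of the 12 DMSO and medium arrays, which were added after values were seen. Where a value moved, the cause was not tested unless stated.

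DMSO against medium kept 0 genes at 48 h under all alternatives. At 24 h it gave 1 gene without DMSO 24 h replicate 1, 1 without both ethanol replicate 3 arrays with the block, and 11 in the blocked fit of 12 arrays. Averaged over both times that fit gave 12, and all other alternatives gave 0. Its difference in time change kept 0 throughout.

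Ethanol against medium at 24 h had 8 genes. It gave 0 after quantile normalization, 0 after median centring, 0 with trend and robust empirical Bayes and 0 with only the groups compared in the fit. It gave 5 at the level of 6, 15 without a level filter, 5 with the mean of probe sets, 5 at 2-fold and 19 with each probe set on its own. Array weights gave 737, the replicate block 111, leaving out both ethanol replicate 3 arrays 144, and this with the block 506. The weights of ethanol 24 h replicate 1, 2 and 3 were 4.31, 1.03 and 0.188. Counts with array weights that use the ethanol 24 h group thus rest largely on its replicate 1. Leaving out 1 array gave 0 without medium 24 h replicate 1, ethanol 24 h replicate 1 or ethanol 24 h replicate 2, 2 without medium 24 h replicate 2, 1 without medium 24 h replicate 3 and 40 without ethanol 24 h replicate 3.

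Ethanol against medium at 48 h had 1654 genes, and 396 at 2-fold, 2587 with each probe set on its own, 114 with only the groups compared, 2811 with the block and 2985 without both ethanol replicate 3 arrays with the block. Leaving out 1 array gave 861 (medium 48 h replicate 3) to 2336 genes, and 1053 without medium 48 h replicate 1. Averaged over both times there were 1329 genes, and 133 at 2-fold, 2218 with each probe set on its own, 608 with only the groups compared, 2484 with the block and 2552 without both ethanol replicate 3 arrays with the block. Leaving out 1 array gave 727 (medium 24 h replicate 1), 852 (medium 24 h replicate 3), 833 (medium 48 h replicate 1), 797 (medium 48 h replicate 3) and 2063 (ethanol 48 h replicate 1).

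DMSO against ethanol at 24 h had 67 genes. It gave 40 after quantile normalization, 34 with the mean of probe sets, 17 at 2-fold, 138 with each probe set on its own, 0 with only the groups compared, 1244 with array weights, 353 with the block, 272 without both ethanol replicate 3 arrays and 806 with the block as well. Leaving out 1 array gave 5, 17 and 26 (DMSO 24 h replicate 1, 2 and 3) and 36, 8 and 101 (ethanol 24 h replicate 1, 2 and 3). At 48 h it had 1934, and 460 at 2-fold, 3058 with each probe set on its own, 174 with only the groups compared, 3143 with the block and 3246 without both ethanol replicate 3 arrays with the block. Leaving out 1 array gave 1098 (DMSO 48 h replicate 3) to 2450 genes, and 1192 without DMSO 48 h replicate 1.

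Time in medium had 0 genes, and 54 with array weights, 438 with the block, 1 with only the groups compared, 42 without both ethanol replicate 3 arrays, 1472 with the block as well and 3227 in the fit of 12 arrays. Leaving out medium 24 h replicate 2 gave 2, and medium 48 h replicate 1 gave 1. Time in DMSO had 0, and 95 with array weights, 257 with the block, 2 with only the groups compared, 30 without both ethanol replicate 3 arrays, 1216 with the block as well and 3083 in the fit of 12 arrays. Time in ethanol had 2493, and 671 at 2-fold, 3865 with each probe set on its own and 95 with only the groups compared, and leaving out 1 array gave 1728 to 2563. Averaged over the controls 3055 passed, and 151 at 2-fold, 4773 with each probe set on its own and 4623 without both ethanol replicate 3 arrays with the block, and leaving out 1 array gave 2296 to 3501.

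The difference in time change between ethanol and medium had 172 genes, and 580 with array weights, 269 with each probe set on its own, 52 with only the groups compared, 508 with the block and 878 without both ethanol replicate 3 arrays with the block. Leaving out 1 array gave 108 and 89 (medium 24 h replicate 1 and 3), 99 and 89 (medium 48 h replicate 2 and 3), 103 (ethanol 24 h replicate 1), and 653 and 109 (ethanol 48 h replicate 1 and 2). Higher counts with each probe set on its own partly follow from more tests, and lower ones at 2-fold from the added threshold.

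With the mean of probe sets 3 named genes turned direction: SPP1 in ethanol against medium at 48 h (adjusted p = 0.0177), B4GALT1 in DMSO against ethanol at 24 h (adjusted p = 0.932) and HSPA4L in time averaged (adjusted p = 0.794). Of the other named gene results under that alternative, 537 stayed, 66 were lost and 1 was gained. The amino acid and integrated stress response list turned direction without medium 48 h replicate 1 in DMSO against medium at 48 h (adjusted p = 0.760) and averaged (adjusted p = 0.903), and with 1 array left out its adjusted p was smallest without medium 48 h replicate 2, at 1.0e-09 and 1.8e-04. Of 84 camera calls, all 84 were lost with an estimated correlation, 33 with fry, 15 without both ethanol replicate 3 arrays, 6 with the replicate block and 0 with median centring. Calls gained under an alternative are not in these counts. Fry called 6 to 17 lists in each comparison that used ethanol 48 h arrays and 0 in each of the others. Of the named gene results, 580 stayed and 27 were lost after quantile normalization, and 496 stayed and 111 were lost without a level filter. With only the groups compared 168 stayed and 327 were lost. There fewer arrays measure the spread, and the ethanol groups also had a higher median SD per gene (0.219 and 0.263) than the others (0.153 to 0.171). These causes were not told apart. Genes under the level could not be tested, and 39.7% to 40.3% of probe sets per array were above it.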

Other observations

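No test of an explanation was run for the values in this part, and the genes shown were chosen after the values had been seen.

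Some genes passed the level for testing on ethanol arrays and on no other array. There were 27 genes above a log2 value of 4 on at least 3 of the 6 ethanol arrays and on none of the other 12, where the same rule gave 2 genes for DMSO and 3 for medium. DMSO and medium arrays were close to each other, which leaves few genes for either alone, so the 2 and 3 are no reference for the 27. Several of the 27 only straddle that level, such as NEBL, with 3.99 as the highest value on the other arrays and 4.11 and 4.71 as the highest with ethanol at 24 h and 48 h. None was above it on all 6 ethanol arrays, and 3 were on 5: a probe set assigned to the microRNA gene MIR146A, PDGFRL, and USP18, an interferon-induced protease, the last of these at 3.98 on the highest other array. IL20RB, a subunit of receptors for interleukins of the IL-20 family, was at 4.59, 4.36 and 5.23 on the 48 h ethanol arrays and at most 3.03 on the 12 others. FBXO16 was at 4.99, 4.70 and 5.54 there and at most 2.95 on the others.

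The ethanol replicates were not alike in all such genes. CDH11, a mesenchymal cadherin, was at 5.28 and 7.77 in replicate 1 and 2 at 24 h and 5.88 and 4.82 at 48 h, but at 2.60 and 2.86 in replicate 3, and at most 2.27 without ethanol. LCN2 was at 12.1 and 13.2 in replicate 3 at 24 h and 48 h and 8.02 in replicate 2 at 48 h, with 3.30 or less on the other ethanol arrays. SCG5, a neuroendocrine chaperone gene, was at 9.32 in replicate 3 at 24 h, where replicates 1 and 2 were at 2.24 and 2.22, and at 5.66, 6.46 and 8.89 at 48 h.

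Markers of other cell types were mostly below the level. Of 12 leukocyte markers on the array 0 passed it, of 10 endothelial markers 1, of 15 keratinocyte markers 1, of 12 fibroblast markers 3, of 7 podocyte and mesangial markers 3, and of 15 distal tubule and collecting duct markers 3. Some of those that passed it differed with ethanol at 48 h against medium, LUM by -1.07 ± 0.26 (adjusted p = 0.0135, limma), PTPRO by -1.08 ± 0.19 (adjusted p = 0.00218) and the keratinocyte gene KRT10 by 0.55 ± 0.11 (adjusted p = 0.00472).

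The time changes were alike in medium and DMSO, whose arrays with the same replicate number also share deviations, so that these changes are not independent. Across 10832 genes, which are not independent replicates, the correlation of the log2 changes was 0.888 between medium and DMSO, 0.561 between medium and ethanol and 0.546 between DMSO and ethanol. The sign was the same for 83.0%, 70.1% and 70.1% of genes.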
